A study of Homo sapiens with 2 samples.

How the data were processed

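Total RNA of 2 cultures of MDA-MB-231 cells was profiled on Agilent single-colour arrays. Per the labels' protocols, RNA was amplified and labelled with Cy3 using the Low Input Quick-Amp kit. The siRNA sequences, dose and time after transfection are not given in the sources used here, and the design text calls the knockdown stable while the labels describe siRNA transfection. Per the file headers, the images were read with Agilent Feature Extraction 10.5.1.1, and the deposited processed signal of each spot is a background-subtracted, detrended intensity on that array's own linear scale, with surrogate values for dim spots and no normalization between arrays. The deposited files also hold the raw mean intensity and local background intensity of each spot, an error for the processed signal from the software's model, and flags for spots well above background, saturated or outlying. Surrogate values compress differences of the dimmest spots, and a fold from a dim probe depends on the background that was subtracted. A value table deposited for the series was set against the scanner files. Its values lay within 1% of the processed signal for 99.2% of 50599 probes in the control column and 99.1% in the HSD3B1 siRNA column, so it is linear, uncentred and unscaled with a known direction. Its column medians were 101.75 and 105.49.

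The sample labelled for HSD3B1 in its title, source name and genotype formed the HSD3B1 siRNA group, and the other sample the control siRNA group, with 1 array in each. Both arrays lay on 1 slide, so slide did not differ between groups. All differences are HSD3B1 siRNA minus control siRNA. The main setting took log2 of the processed signal and subtracted each array's 75th percentile over all spots other than controls, which was 1503.1 on the control array and 1253.6 on the HSD3B1 siRNA array. The median spot signal was 136.7 on both. Control spots were left out, as were spots flagged as outliers on either array (227 on the control array and 391 on the other), and spots of one probe were averaged. A gene took the value of its probe with the highest mean normalized log2 signal, and it was measured if that probe was well above background on at least 1 array. Of 36399 gene names, 26260 were measured, 15768 of them protein-coding, and 10139 were not well above background.

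Probes were named through a table of RefSeq genes of assembly GRCh38.p14, used for names and gene types only. Of 50599 probes, 28174 were named by accession, 2618 by symbol and 619 by an older symbol, and 19188 kept the name in the file. Probe positions are those of the files, in hg19. No annotation of hg19 was used here, so exons and untranslated regions were not assigned.

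With 1 array per group no test between groups is possible, and no p-value is given. Genes were counted at 2-fold, and members of lists at 1.5-fold. Each of 32 gene lists, chosen with the design, the rule for named genes and the alternative settings before the data were examined, was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size drawn from measured genes and matched on mean signal in 20 bins. A list was said to stand apart where its median lay in the lowest or highest 2.5% of random lists. The percentile describes these 2 arrays and is not a test of the siRNA. On simulated lists of 20 genes placed on the 26260 measured genes of this comparison, 5 of 100 lists with no shift stood apart. So did 2 of 2 lists shifted by 0.3, 4 of 4 shifted by 0.585 and 4 of 4 shifted by 1 on the log2 scale, with the right sign. The simulated differences had independent noise in each gene, so they do not show how often lists of co-regulated genes stand apart between 2 cultures.

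The genes named in the text were HSD3B1 and HSD3B2, and the 12 highest and 12 lowest protein-coding genes among those well above background and unsaturated on both arrays, at or above the median signal, with all such probes of one sign (6394 of 7415 genes). They also included up to 2 highest and 2 lowest members of each list past 1.5-fold, or the largest difference where none was, and up to 5 genes in each direction well above background on 1 array only. For the last, the fold is a lower bound against the higher of the dim probe's value and the lowest signal among probes well above background on that array. Other genes are said to have been chosen after their values were seen, and HSD3B7 was added in that way. Some genes that the rule selects are not reported here.

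The alternatives chosen at that point were normexp background correction (offset 50) on the mean and background intensities, quantile normalization, intensity-dependent loess of the difference on the mean signal (span 0.4), scaling on the median of probes well above background on both arrays, the deposited value table without scaling, the median over the probes of a gene, a filter requiring both arrays above background, no such filter, outlier spots kept, 1.5-fold and 3-fold in place of 2-fold, and random lists without matching on signal. Scaling on the 8 of 10 spike-in controls that were well above background and random lists of protein-coding genes only were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. The precision of a value is limited by the number of arrays, and the errors given for single spots cover the scan of 1 spot and not the culture.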

Results

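RNA was measured in MDA-MB-231, an established human cell line from a triple-negative breast cancer, which lacks the receptors for oestrogen and progesterone and has no HER2 amplification. One culture had been transfected with a negative control siRNA and the other with siRNA against HSD3B1. HSD3B1 encodes a hydroxysteroid dehydrogenase that converts precursor steroids such as pregnenolone and dehydroepiandrosterone into progesterone and androstenedione, so the comparison asks which transcripts differ when this enzyme is targeted. Each group had 1 array, and both arrays lay on the same slide. Every difference below therefore has no replicate check: it describes these 2 arrays, carries no p-value and cannot be set against the spread between cultures. Each array held 58717 spots of 50599 probes apart from controls. The share of these spots well above background was 65.7% on the control siRNA array and 70.2% on the HSD3B1 siRNA array, and no spot was saturated. Of 36399 gene names on the array, 26260 were measured, meaning that their probe was well above background on at least 1 array.

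The targeted transcript was lower in the culture that received HSD3B1 siRNA. The single HSD3B1 probe (A_24_P350397, transcript NM_000862, hg19 chromosome 1 from 120057251 to 120057311) gave a processed signal of 225 ± 23.9 on the control array and 58.6 ± 8.8 on the HSD3B1 siRNA array, where the errors come from the extraction software's model of 1 spot. After scaling, the log2 difference was −1.68 (SE 0.27 from the same model), which left 31.3% of the control level. Only 18 of 3359 genes of similar signal (0.54%) were as low or lower. HSD3B1 was dim, and with a normexp background correction that also adds an offset of 50 signal units to each spot its difference was −0.97. Correction and offset were not run apart. The probe of HSD3B2, its close relative (A_23_P51580, NM_000198, hg19 chromosome 1 from 119964672 to 119964731), read 76.1 on the control array and 71.1 on the HSD3B1 siRNA array. Its log2 difference of 0.16 (SE 0.27) was within the spot error and took the other sign under quantile normalization, loess and the unscaled value table. HSD3B7, an enzyme of bile acid synthesis in the same family, had a log2 difference of 0.70 (SE 0.20). The description attached to the HSD3B1 siRNA sample repeats the wording of the control, while its title, source name and genotype name HSD3B1, and the sample was grouped by the latter.

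Among bright protein-coding genes, the lowest in the HSD3B1 siRNA culture were mediators of inflammation and of the acute phase. The chemokine gene CXCL2 was 7.24-fold lower, with log2 differences of −2.86 and −2.46 at its 2 probes. The acute-phase proteins SAA2 and SAA1 were 6.14-fold and 3.97-fold lower, although their transcripts are similar enough for a probe of one to bind the other. IL6, an inflammatory cytokine, was 4.75-fold lower, and STING1, the adaptor that relays the sensing of cytosolic DNA, 4.56-fold lower. IGFBP1, which binds insulin-like growth factors, was 5.30-fold lower. Other genes of this group were YWHAG (5.15-fold lower), a phosphoserine-binding adaptor, LHFPL2 (3.99-fold), ODC1 (3.68-fold), the rate-limiting enzyme of polyamine synthesis, and BATF3 (3.61-fold), a leucine zipper transcription factor. DNM1L, the GTPase of mitochondrial fission, was 3.46-fold lower, with log2 differences between −1.87 and −0.45 over 3 probes.

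The genes that were highest in the HSD3B1 siRNA culture by the same rule included 4 whose proteins work in the lysosome. These were ASAH1 (2.85-fold higher), the acid ceramidase, SLC17A5 (2.79-fold), the sialic acid exporter, IDUA (2.72-fold), which degrades glycosaminoglycans, and SLC36A1 (2.44-fold), an amino acid transporter. SLAMF7, a receptor best known from immune cells, was 3.15-fold higher. EVC, a protein of the primary cilium, was 2.92-fold higher, ALPP, the placental alkaline phosphatase, 2.88-fold, SPNS2, a transporter of sphingosine phosphate, 2.80-fold, and HTT, which encodes huntingtin, 2.79-fold. EBF4 (2.69-fold), the matricellular protein gene CCN3 (2.53-fold) and the cation channel gene TMEM38A (a log2 difference of 1.33, over 7 spots) completed the 12. Each gene named in these lowest and highest groups differed by at least 2-fold in the same direction under each of the 10 alternative settings. Most of them had a single probe well above background on both arrays. Further probes well above background on at least 1 array, those of CXCL2, SAA2, IL6, DNM1L, SLC17A5 and EVC, had the same sign. For CXCL2, DNM1L, SLC17A5 and EVC this agreement was required by the rule that chose the genes. The further probes of SAA2 and IL6 were dim, at −2.40 and −1.07. Both were well above background on the control array only, which favours a lower value on the other array.

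**Figure D1:**
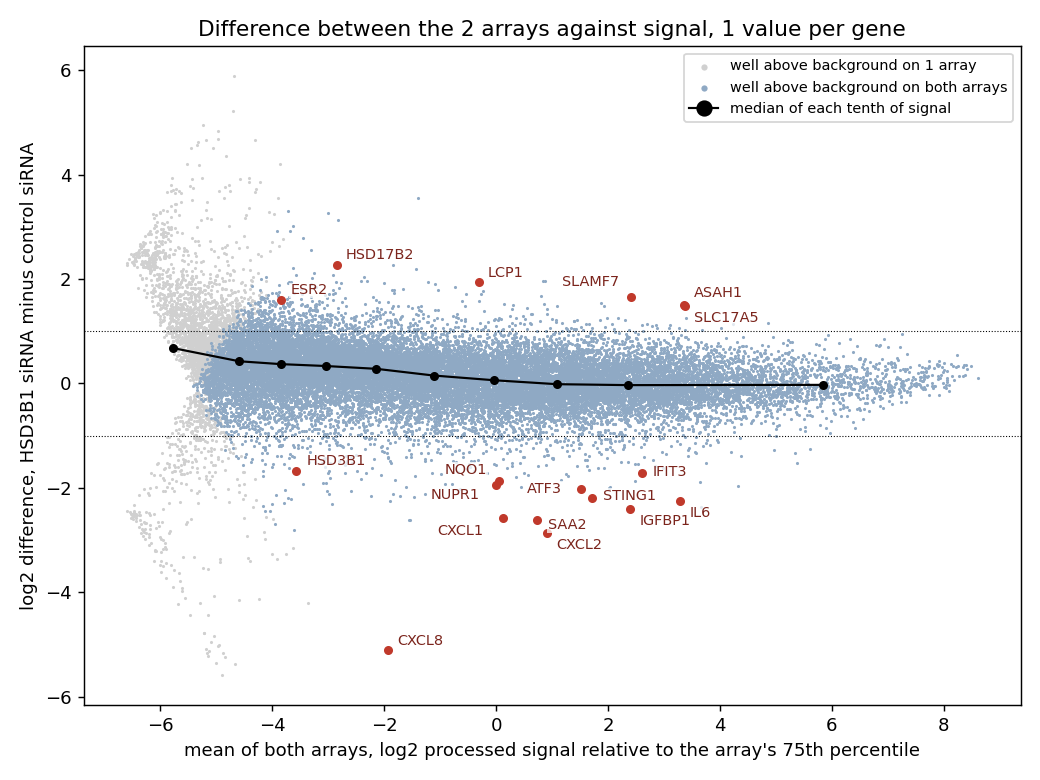
Log2 difference between the arrays (HSD3B1 siRNA minus control siRNA) for each of 26260 genes against its mean log2 signal relative to the array's 75th percentile, with grey points for genes well above background on 1 array only, red points for named genes and dotted lines at 2-fold. The black line joins the medians of 10 equal signal bins and runs from 0.68 in the dimmest to −0.03 in the brightest, and CXCL8 stands at −5.11.

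At 2-fold, 1964 genes were higher and 712 lower in the HSD3B1 siRNA culture, so 73.4% of the genes past that size were higher. Protein-coding genes well above background on both arrays were close to even, at 377 higher and 336 lower of 14829. The excess of higher genes lay among dim ones: in the dimmest of 10 equal signal bins 942 genes were higher and 235 lower, with a median log2 difference of 0.68, while in the brightest bin 11 were higher and 30 lower, with a median of −0.03. The share of higher genes differed between settings. It was 50.7% after an intensity-dependent loess (1100 higher, 1069 lower), 52.5% after quantile normalization (1132 and 1026), 51.4% after normexp (353 and 334), 60.0% when scaled on the median of probes well above background (1478 and 986), 72.5% when scaled on the spike-in controls (1920 and 730) and 47.4% in the unscaled value table (1165 and 1294). The median of all genes was 0.19 in the main scaling, 0.18 after normexp and with spike-in scaling, 0.07 after quantile normalization, 0.05 after loess and after scaling on the median of probes well above background, and −0.07 in the unscaled table. Gene lists were set against random lists of genes of the same signal. At one signal protein-coding genes could still lie below other names (medians of 0.07 and 0.30 in the sixth bin), so random lists of protein-coding genes only were run as well.

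Of the genes well above background on 1 array only, 765 protein-coding genes were seen on the HSD3B1 siRNA array and 158 on the control array, and 173 and 38 of them differed by at least 2-fold as a lower bound. CAGE1, a cancer-testis antigen, was at least 9.17-fold higher in the HSD3B1 siRNA culture, followed by RND2 (at least 8.05-fold), SEMG1 (7.35-fold), PLXDC1 (6.79-fold) and SPINT3 (6.75-fold). On the control array alone, FAM9A was at least 10.48-fold brighter, LRFN2 9.66-fold, ECSCR 9.59-fold and CPB2 8.92-fold. AKR1D1, which reduces the double bond of steroid hormones and bile acid precursors, was at least 9.14-fold lower in the HSD3B1 siRNA culture. Each bound sets the brighter array against the higher of the dim probe's own value and the dimmest probe well above background.

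Genes of inflammation and of the interferon response were lower together. Of 28 measured cytokines, chemokines and NF-kB targets, 14 were at least 1.5-fold lower and 0 were higher, and the median log2 difference of −0.65 lay below all 10000 random lists of the same size and signal (percentile 0). CXCL8, a neutrophil-attracting chemokine, was 34.4-fold lower (log2 difference −5.11), though its value came to −3.32 as the median over its probes and to −4.13 with normexp. The related chemokine CXCL1 was 6.01-fold lower, with −2.59 and −1.88 at its 2 probes. Further members, named after their values were seen, were CXCL3 at −2.21, IL1A at −1.60, the apoptosis inhibitor BIRC3 at −1.46 and SOD2, the mitochondrial superoxide dismutase, at −0.94, whereas TNF was at −0.19, NFKBIA at −0.44 and TNFAIP3 at 0.38. IL6 was at −2.25 and came to −1.66 as the median over its probes. Of 32 interferon-stimulated genes, 16 were at least 1.5-fold lower and 0 were higher, with a median of −0.54 and percentile 0. The antiviral genes IFIT3 and IFIT2 led them with log2 differences of −1.71 and −1.32. Members on either side, also named after their values were seen, were RSAD2 at −1.25, MX1 at −0.20, ISG15 at −0.19 and OAS3 at 0.29.

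Targets of the unfolded protein response and of the transcription factor ATF4 had the lowest median of all 32 lists, −0.95, with 18 of 28 genes at least 1.5-fold lower, 0 higher and percentile 0. The transcription factor gene ATF3 was 4.08-fold lower at its brightest probe, but its 4 probes ranged from −2.03 to 0.33 and their median was −0.98. NUPR1, a stress-induced nuclear protein, was 3.82-fold lower, and SESN2, which restrains growth signalling when amino acids are scarce, 2.88-fold. Both arms of the list were represented among members named after their values were seen. The asparagine synthetase gene ASNS was at −1.47, the pseudokinase gene TRIB3 at −1.39, the chaperone gene HSPA5 at −1.25 and ATF4 itself at −0.69, whereas the chaperone genes HSP90B1 and CALR were at 0.16 and 0.24. Genes of the NRF2 response to oxidative stress had a median of −0.57 and percentile 0, with 10 of 20 at least 1.5-fold lower and 0 higher. NQO1, the quinone reductase, was 3.63-fold lower and AKR1C1, an aldo-keto reductase that also inactivates progesterone, 3.42-fold lower, the latter at −0.89 as the median over its probes. Members chosen after their values were seen, the haem oxygenase gene HMOX1 and the glutamate-cysteine ligase subunits GCLC and GCLM, were at −1.11, −0.49 and 0.28. Heat shock genes had a median of −0.26 and percentile 0.45, although 13 of 16 differed by less than 1.5-fold. DNAJB4 and HSPH1 were lower at −0.69 and −0.62, while the small heat shock protein gene HSPB1 was higher at 0.74.

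Genes of cholesterol synthesis were lower along most of the pathway. Of 24 SREBP2 targets, 17 were at least 1.5-fold lower and 0 were higher, with a median of −0.78 and percentile 0. HMGCS1, a synthase early in the pathway, was 2.44-fold lower. Further steps, named after their values were seen, were the squalene epoxidase SQLE at −1.15 and the farnesyl diphosphate synthase FDPS at −0.87. Of others named in that way, LSS was at −0.34 at its brightest probe but at 0.49 at another, and the phosphomevalonate kinase PMVK was at 0.39. The 16 SREBP1 targets of fatty acid synthesis had a median of −0.07 and percentile 25.2, with 5 lower and 1 higher at 1.5-fold. TMEM97 and the malic enzyme ME1 were 2.13-fold and 2.03-fold lower, and with the median over each gene's probes the list came to percentile 1.92. Genes of cholesterol efflux driven by LXR gave a median of 0.17 and percentile 79.5 over 11 genes. APOE and the sterol exporter ABCG1, the latter dim, were higher at 0.94 and 0.88, and APOC1 was lower at −0.80.

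Mitotic genes were lower as a group, most of them by less than 1.5-fold. At the brightest probe all 30 genes of G2 and mitosis had differences below 0, with a median of −0.40 and percentile 0, and 7 passed 1.5-fold. CDK1 and MKI67, named after their values were seen, each also had a probe above 0, at 0.40 and 0.47. HMMR, a spindle protein, and the checkpoint kinase BUB1 were 1.79-fold and 1.77-fold lower. The 32 genes of S phase and DNA replication had a median of −0.05 and percentile 26.4. Among them the flap endonuclease FEN1 and the replication factor GINS1 were lower at −1.13 and −0.80, and RFC5 was higher at 0.59. The p53 targets gave a median of 0.00 and percentile 18.2 over 23 genes, with 2 higher and 3 lower at 1.5-fold, among them BAX and FDXR at 0.69 and 0.66 and SESN2 and DDB2 at −1.53 and −0.71. Over 21 regulators of apoptosis the median was −0.13 and the percentile 6.14. HRK, from a dim probe, was higher at 1.05, and MCL1 was lower at −0.97. CFLAR was at −1.10 at its brightest probe but at 0.00 as the median over its probes.

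The lists closest to the targeted enzyme did not stand apart from random lists. The 31 measured genes of steroid hormone synthesis and metabolism had a median of 0.18 and percentile 55.9, with 7 higher and 5 lower at 1.5-fold. HSD17B2, which oxidises oestradiol and testosterone to weaker forms, was 4.83-fold higher and HSD17B3, which makes testosterone, 1.95-fold higher, both from dim probes, and HSD17B2 came to 1.62 on the log2 scale with normexp against 2.27. AKR1C3, which also makes testosterone, was 2.21-fold lower. Steroid receptors and their co-regulators had a median of 0.18 and percentile 54.1 over 18 genes. The oestrogen receptor gene ESR2 was higher at 1.60, or 0.996 with normexp, and the orphan receptor gene ESRRG at 0.79, both dim. Oestrogen-responsive genes gave a median of 0.09 and percentile 41.1 over 19 genes. NRIP1 and CXCL12, the latter dim, were higher at 1.08 and 0.72, and XBP1 was lower at −1.02. MYC was at −0.91 over the 10 spots of its bright probe and at 0.43 at a dim one. Genes responsive to androgen or glucocorticoid had a median of −0.10 and percentile 2.87, with 6 of 22 lower and 2 higher at 1.5-fold. SGK1 and FKBP5 were lower at −1.19 and −0.98, and ZBTB16 and KLK2, both dim, were higher at 1.01 and 0.65. The list came to percentile 0.85 after loess and 1.04 after quantile normalization.

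Epithelial genes were lower as a group, and the other lists of adhesion and invasion had members on both sides. Epithelial junction and keratin genes had a median of −0.25 and percentile 0.07, with 7 of 24 lower and 1 higher at 1.5-fold. The cadherin gene CDH1 and the claudin gene CLDN3 were both 2.82-fold lower, and the junction protein gene TJP3 was higher at 0.62. CDH1 and TJP3 were dim, and under the alternative nearest 0 they came to −0.92 and 0.28, against −1.28 for CLDN3. Mesenchymal and invasion genes had a median of −0.01 and percentile 25.9, with 9 of 31 lower and 1 higher. PLAU, the urokinase, was 2.89-fold lower, and CDH2, from a dim probe, was higher at 0.62. Targets of TGF-beta and SMAD had a median of −0.17 and percentile 0.86 over 20 genes, with 6 lower and 3 higher at 1.5-fold. INHBA was lower at −0.89, but the BMP-responsive genes ID3 and ID2 were higher at 1.49 and 0.78. ID2 was dim, and another of its probes was at 0.03. Matrix proteases and their inhibitors had a median of 0.32 and percentile 96.8, with 7 of 20 higher and 1 lower at 1.5-fold. MMP15 and TIMP3 were higher at 1.58 and 1.13, and PLAT, the tissue plasminogen activator, was lower at −0.83. That list passed the limit after loess (99.8), quantile normalization (99.7) and normexp (98.1), and against random lists of protein-coding genes (98.4).

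Angiogenic factors had a median of 0.10 and percentile 42.0, with 5 higher and 5 lower of 22. FGF5, which was dim, and VEGFB were higher at 1.63 and 0.79, while CXCL8 and CXCL1 belong to this list too. Targets of YAP and TEAD had a median of −0.15 and percentile 6.10 over 20 genes, or 2.17 after loess, with 4 lower and 0 higher at 1.5-fold, among them NUAK2 and CCN2 at −0.97 and −0.96. Feedback and immediate early genes of the MAPK pathway had a median of −0.02 and percentile 24.6, with 5 of 24 lower and 0 higher. The EGF receptor ligand genes AREG and EREG were lower at −1.32 and −1.09.

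The lists of glycolysis, oxidative phosphorylation, ribosomal proteins, small RNA machinery and histones did not stand apart from random lists in the main setting. Genes of hypoxia and glycolysis had a median of 0.01 and percentile 54.6 over 33 genes, with PFKL and VEGFA higher at 0.87 and 0.77 and HK1 lower at −0.64. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.00 and percentile 65.4, and NDUFS1, at −0.62, was the only member of 33 past 1.5-fold. Cytosolic ribosomal protein genes had a median of −0.08 and percentile 8.88, or 0.01 after quantile normalization, with RPS9 at −0.63 the only member of 39 past 1.5-fold. The microRNA and siRNA machinery had a median of −0.13 and percentile 13.4 over 14 genes, and PRKRA was at −0.67. Replication-dependent histones had a median of 0.22 and percentile 93.2 over 16 genes, or 98.1 with the median over each gene's probes. H2AC6 and H2AC8 were at 0.83 and 0.62, but dimmer probes of H2AC6 were at 0.36 and −0.05.

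Markers of cells other than MDA-MB-231 were measured beside these groups. Leucocyte markers had a median of 0.49 and percentile 98.8, with 6 of 16 higher and 1 lower at 1.5-fold. LCP1, an actin-bundling protein of leucocytes that many tumour lines also make, was 3.84-fold higher and CD163 2.03-fold, whereas LAPTM5 was 3.30-fold lower. The CD163 probe was dim. Fibroblast, endothelial and adipocyte markers had a median of −0.20 and percentile 0.42, with 3 of 11 lower and 1 higher. PDGFRB and COL1A2 were lower at −1.05 and −0.99 and LUM, from a dim probe, was higher at 2.04. Markers of luminal breast cancer lines had a median of −0.28 and percentile 0.42, with AGR2 lower at −1.58 and ERBB3 higher at 1.01, but the list came to percentile 8.11 when genes had to be well above background on both arrays. Melanocyte lineage markers had a median of 0.18 and percentile 23.8, below the 0.30 of random lists of their dim signal, with CAPN3 and MLANA higher at 1.15 and 1.14 and MIA lower at −1.03.

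**Figure D2:**
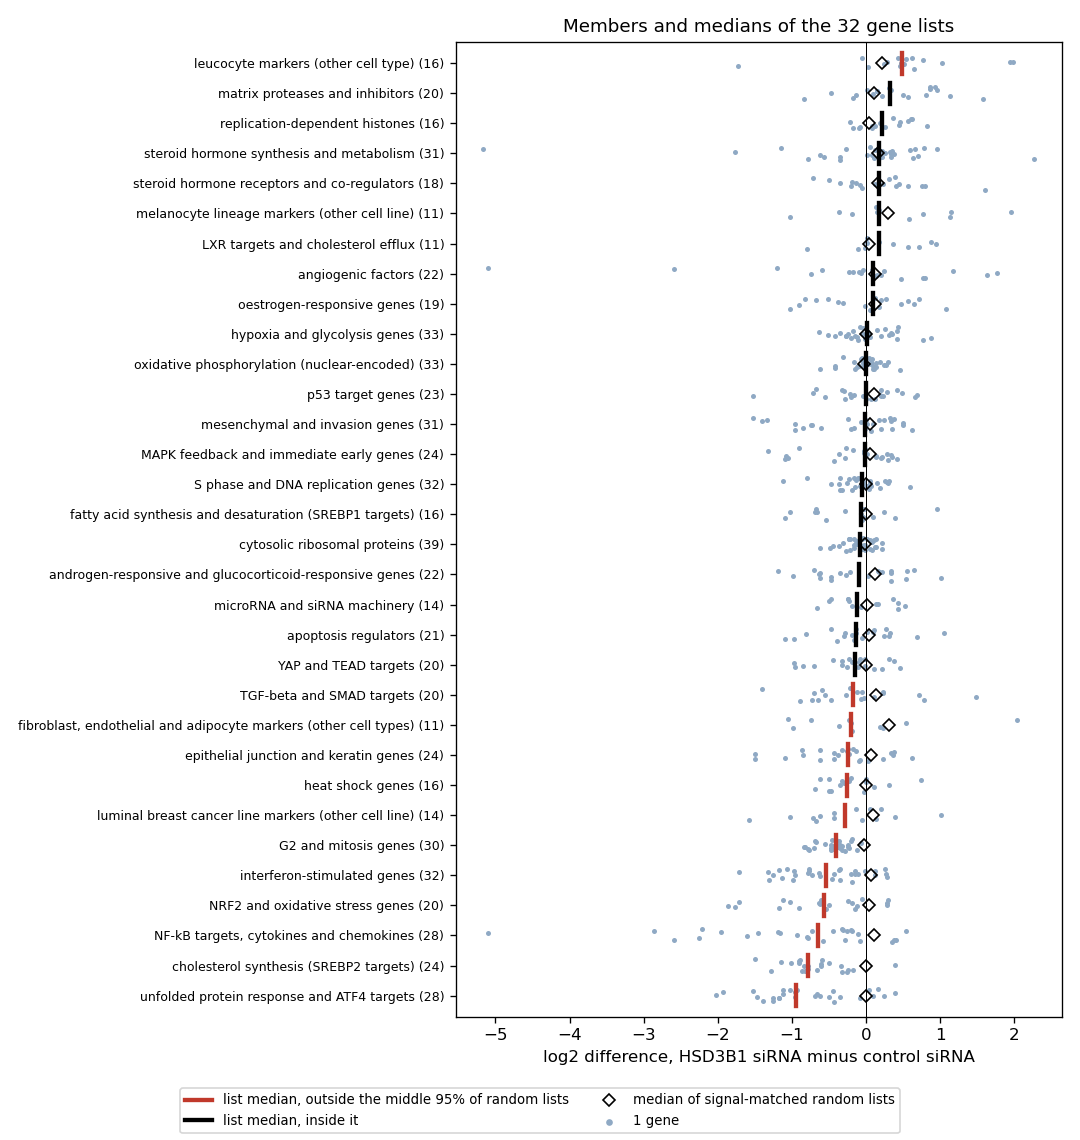
Log2 difference (HSD3B1 siRNA minus control siRNA) of every measured member of the 32 gene lists, 1 point per gene, with the number of measured genes in brackets, the list median as a bar and the median of signal-matched random lists as a diamond. Red bars mark the 12 lists outside the middle 95% of random lists, 11 of them lower, from −0.95 for targets of the unfolded protein response and ATF4 to −0.17 for TGF-beta targets, and leucocyte markers higher at 0.49.

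In all, 12 of the 32 lists lay in the lowest or highest 2.5% of random lists. Of these, 11 were on the lower side and 1 on the higher. Among 32 lists of genes picked at random, 1.6 would be expected there. Members of a list can vary together and several lists share members, so 1.6 is not the number expected between any 2 cultures. The sign of the median held under every alternative for those 12 lists and turned under at least 1 alternative for 11 of the other 20. The median and the mean of the members had opposite signs in 4 lists, those of steroid synthesis (0.18 and −0.04), oestrogen-responsive genes (0.09 and −0.01), angiogenic factors (0.10 and −0.15) and oxidative phosphorylation (0.00 and −0.01). Without the member furthest from 0 the mean took the sign of the median in the steroid list (0.13 without AKR1D1, which was not above background on the HSD3B1 siRNA array), the angiogenic list (0.09 without CXCL8) and oxidative phosphorylation (0.01 without NDUFS1), but not in the oestrogen list (−0.07 without NRIP1).

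The error that the arrays themselves show was small for a single probe and larger between probes of one gene. Over 744 probes printed 10 times and well above background, the SD of the log2 difference between spots had a median of 0.07 and a 95th percentile of 0.37. Over 5519 genes with at least 2 different probes well above background on both arrays, the SD between probes had a median of 0.22 and a 95th percentile of 0.74. Of 277 genes whose first probe differed by at least 2-fold, the second probe had the same sign in 80.1% and passed 2-fold with that sign in 24.9%. Neither figure contains the spread between cultures, and the number of arrays limits the precision of every value.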

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

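No paired analysis was possible because each group has 1 array, and no replicate could be left out. Scaling on spike-in controls and random lists of protein-coding genes were chosen after seeing the data. Of the 12 lists that stood apart, 11 did so under every alternative run. Their percentiles reached at most 2.26 on the lower side (heat shock genes) and at least 97.7 on the higher (leucocyte markers). Scaling on spike-in controls or on the median of probes well above background shifts all genes alike, so it could not move a percentile. The unscaled value table does nearly the same, and the values of these settings are counted below as having kept their side of the limits. The alternatives for single genes were run on 106 genes, which are HSD3B1, HSD3B2, the 12 highest and 12 lowest and the leading members of lists, and none of these past 1.5-fold took the other sign under any of the 10. Genes above background on 1 array only and genes chosen after their values were seen were not rerun singly. The following values moved, and where no reason is stated the cause was not tested. Genes at least 2-fold higher and lower numbered 353 and 334 with normexp, 1132 higher with quantile normalization, 1100 and 1069 with loess, 1165 and 1294 in the unscaled value table, 746 and 426 with both arrays above background, 3225 and 1294 without a filter, 5398 and 2000 at 1.5-fold and 662 and 280 at 3-fold, the last 4 pairs because the filter or limit itself admits other genes. HSD3B1 was at −0.97 with normexp, −1.98 with quantile normalization and −1.997 with loess. Luminal markers no longer stood apart with normexp (percentile 5.24), with both arrays above background (8.11) or without a filter (9.13). Lists that stood apart only under an alternative were matrix proteases with normexp (98.14), quantile normalization (99.73), loess (99.84) and random lists of protein-coding genes (98.4), and androgen-responsive and glucocorticoid-responsive genes with quantile normalization (1.04), loess (0.85), the median over probes (2.26) and unmatched random lists (1.6). Ribosomal protein genes did so with quantile normalization (0.01) and unmatched lists (0.31), YAP targets with loess (2.17) and unmatched lists (0.69), fatty acid synthesis (1.92) and histones (98.13) with the median over probes, and S phase genes (1.29) and apoptosis regulators (1.02) with unmatched lists. Among single named genes 347 values moved by more than the median SD between spots and 703 did not, and among lists 365 kept their side of the limits, 16 gained and 3 lost their place outside them. The lowest signal bin held 942 of the 1964 higher genes. With normexp 344 of the 1964 stayed at least 2-fold higher, and 326 of the 712 lower genes stayed at least 2-fold lower. That setting changes the background correction and adds an offset of 50 signal units, which by itself shrinks the folds of dim probes, and the 2 were not run apart.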

Other observations

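Tests chosen only after the result was seen were those of the dim genes and those of the 5 lower lists and of the lysosomal genes after loess and between single cultures, and the lists of lysosomal, autophagy, synthetase and proteasome genes were drawn up after the leading genes were known. Genes of the lysosome were higher as a group in the HSD3B1 siRNA culture. Of 45 lysosomal enzymes, membrane proteins and transporters, 18 were at least 1.5-fold higher and 0 were lower, with a median log2 difference of 0.51 against −0.004 for random lists of the same signal. CTSZ, a cysteine protease, was at 1.97, but it missed the signal limit or the agreement of probes required of the 12 highest genes. The acid glucosidase GAA was at 1.25, the protease CTSF at 0.93 and CTSA at 0.78. The sphingolipid activator precursor PSAP was at 0.60 and the membrane protein LAMP1 at 0.51. The trafficking channel MCOLN1 was at −0.50 and the sterol transporter NPC1 at −0.02. Autophagy genes did not share this, with a median of −0.02 and percentile 39.7 over 25 genes, among which GABARAPL1 was at −0.99, MAP1LC3B at −0.37, SQSTM1 at 0.46 and the lysosomal regulator TFEB at 0.62.

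Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, had a median of −0.39 and percentile 0 over 20 genes, with 5 at least 1.5-fold lower and 0 higher, led by LARS1 at −0.89 and WARS1 at −0.86. Proteasome subunits had a median of −0.29 and percentile 0.01 over 30 genes, with PSMD3 at −1.03 the only member past 1.5-fold. Within the unfolded protein response list, the 18 ATF4 targets had a median of −0.96 and the 10 endoplasmic reticulum chaperones and XBP1 or ATF6 targets a median of −0.72, both at percentile 0.

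The higher lysosomal genes may reflect a set and not 4 single genes. Without ASAH1, SLC17A5, SLC36A1 and IDUA, which prompted the test, the other 41 genes had a median of 0.43 and percentile 100, with 14 at least 1.5-fold higher and 0 lower. The signal-dependent difference between the arrays is argued against as the whole source, since random lists of the same signal had a median of −0.002. After loess, which takes the trend with signal out of all genes, the same 41 genes had a median of 0.48 (95% bootstrap interval 0.236 to 0.582). With so little trend at their signal, loess could hardly have moved that median, so it is no separate evidence. This interval and those below resample genes within these 2 arrays. They cover neither members that vary together nor the spread between cultures. Whether the siRNA target or a difference between 2 single cultures lies behind the higher lysosomal genes stays open with 1 array per group.

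The 5 lists of NF-kB targets, interferon-stimulated genes, ATF4 and unfolded protein response targets, NRF2 genes and SREBP2 targets of cholesterol synthesis were lower together. A signal-dependent difference between the arrays is argued against by random lists of the same signal. In the order above, their medians were 0.10, 0.07, 0.0004, 0.04 and −0.003. The list median nearest 0 after loess was −0.54 (NRF2 genes, 95% bootstrap interval −0.95 to −0.161). With so little trend at these signals, loess could hardly have moved the medians, so it is no separate evidence. Shared members are argued against, because the highest of the 5 percentiles was 0 once every gene held by more than 1 of the 32 lists was left out. Few genes were shared, so little was removed. In the order above, 26 of 28, 32 of 32, 25 of 28, 17 of 20 and 23 of 24 genes remained. For lower ATF4 output beyond the fixed list, the aminoacyl-tRNA synthetases had percentile 0, where a value above 10 would have spoken against it. A low percentile was not particular to them. The proteasome subunits were at 0.01 and 11 of the 32 lists stood apart on the lower side, so the synthetases do not decide whether ATF4 output was lower. A difference between 2 single cultures unrelated to the siRNA target, such as density or medium, cannot be told apart from an effect of HSD3B1 siRNA, because each group has 1 array. No siRNA of another sequence was analysed here, so effects of the siRNA on other transcripts also stay open.

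Dim genes were higher on the HSD3B1 siRNA array, with a median of 0.68 in the dimmest of 10 signal bins. Genes entered if well above background on either array, and 765 protein-coding genes were so on the HSD3B1 siRNA array only, against 158 on the control array only. This filter can raise the median of dim genes, and its part in the 0.68 was not tested. Without a filter the median of all genes was 0.12 against 0.19, and 71.4% of the genes past 2-fold were higher. The filter acts on every gene type, so the first-bin comparison of types below cannot tell it apart. A single scale factor is argued against by the spike-in controls, whose median after scaling was 0.011 (range −0.106 to 0.158). A single additive offset is argued against because the offset needed was 15.2 signal units in the first bin and 60.1 in the sixth, a ratio of 3.95, with intervals that do not overlap (14.5 to 15.9 and 50.8 to 69.4). A difference that depends on signal whatever the gene was not settled. In the first bin, names matched to neither a protein-coding nor an lncRNA gene and protein-coding genes differed by 0.002 (95% bootstrap interval −0.085 to 0.096). It is argued against in the sixth bin, where they differed by 0.226 (0.191 to 0.263, medians 0.30 and 0.07). Spike-in a107 was at 0.10 against a gene median of 0.43 in the second bin, and a135 at −0.04 against 0.15 in the sixth. Spike-in a20 was at 0.16 against 0.06 in the seventh. Each is a single control sequence that the filter on genes did not select, so these values do not settle it. The class of other names can hold coding genes whose names were not found in the reference. What separates the classes in the sixth bin was not tested, and it stays open between a property of the probes and a difference in the RNA.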
